A study of Mus musculus with 6 samples.

How the data were processed

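Messenger RNA was sequenced from sorted bone-marrow pro-B cells of C57BL/6 mice aged 4 to 6 weeks, in 3 libraries from Chd4 conditional knockout animals (cKO) and 3 from wild-type littermates (WT). Per the labels' protocols, polyadenylated RNA was captured from 50 ng of total RNA with oligo-dT beads and made into libraries with a stranded kit. The labels call the samples biological replicates and the series' design text calls them independent RNA samples.

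The authors deposited 1 table of raw read counts per gene, with a column for each library and no pooling. Per the file headers, reads were counted with featureCounts 1.5.2 against Ensembl 67 genes on mm9, with strand setting 2 (reverse-stranded). The recorded command gave neither the option for multi-mapping reads nor the option for reads that overlap several genes. Reads shared by near-identical copies, such as immunoglobulin variable segments, and reads in overlapping genes of 1 strand are therefore under-counted, and antisense partners are kept apart by strand. Per the submitters' processing notes, STAR 2.4.1d and Subread 1.5.2 were used on mm9, together with bcl2fastq, whose version is not given in the sources used here. Read trimming and alignment settings are not given in the sources used here.

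The table held 37620 Ensembl gene IDs, of which 14832 had no count in any library. Symbols were taken by ID from the table of gene names given with GENCODE M21, and 32897 IDs matched. The other 4723 IDs kept their Ensembl name and held between 0.697% and 0.791% of each library's counts. Coordinates are those of the deposited table (mm9), and the GRCm38 genome was not used for positions. No row without a gene name was present, and all per-sample columns were used.

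The library totals ranged from 22626801 to 30863754 counts. Within a group, chi-square per degree of freedom between libraries over genes with at least 10 counts was between 14.7 and 29.3, so no pair of libraries differed by as little as sampling noise. The counting intervals and floors (95%, 3 counts over the group for a gene at 0) cover counting error only, since the reads carry no molecular identifiers.

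Differences between cKO and WT were tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM factors (0.993 to 1.01), filterByExpr (minimum count 10, minimum total 15), the quasi-likelihood F test and Benjamini-Hochberg adjustment over the 14063 genes tested. A gene was called changed at an adjusted p under 0.05, and the standard error is the log2 fold change divided by the square root of F. CPM values are scaled by the TMM factors, and means and SDs are over 3 libraries. The code was tested on simulated data for the comparison of cKO with WT, over 13913 genes. There 79.6% of 98 genes changed by 0.75 and 95.9% of 98 genes changed by 1.5 on the log2 scale were recovered, and 11 of 183 calls (6.01%) were false. The simulation gave all genes a single common dispersion and changed few of them. Its rates therefore check the code and do not carry over to data with gene-specific spread and many changed genes.

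Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with the adjustment over the 28 of 31 lists that had at least 5 tested members. The correlation was also estimated per list, and fry was run as a self-contained test. Expression bins split the tested genes into 4 parts by mean log2 CPM over all 6 libraries, with Wilson 95% intervals on shares. Immunoglobulin variable families were summed per library and compared by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1.

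The tests, the lists (20 of pathways and complexes, 11 of cell type, handling and sex markers) and the rule for named genes were fixed before the data were examined. The rule named Chd4, then Cd79a, Cd19, Kit, Ebf1, Pax5, Rag1, Rag2, Il7r, Dntt, Igll1 and Vpreb1, then the 6 largest rises and 6 largest falls among called genes with a mean CPM of at least 5 and no overlap between the groups. Immunoglobulin and T-cell receptor segments and symbols of the Gm and Rik kind were left out of that last part, and IDs without a symbol were left out too. For each list the rule allowed up to 3 called members with the smallest p, or up to 2 with the highest mean CPM where none was called. Kcna5, S100a9 and the genes of the closing section were named outside the rule.

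The groups share the replicate numbers 1 to 3, and the labels do not say what a number marks. The correlations of deviations from the group means were 0.182, 0.187 and 0.367 for libraries of the same number. All were above 0.1, and each was the highest for its cKO library, although WT 2 and cKO 1, of different numbers, reached 0.168, close to the 0.182 of the first pair. By these values the numbers were taken to pair the samples, from the data and not from a statement in the labels. The titles carry consecutive identifiers for libraries of the same number, but the labels do not say what these mark. Only replicate 3 of either group carried Y-linked reads beyond a few counts, so the 0.367 of that pair was not separated from sex. The fit with the replicate number as a block was an alternative from the start, and its values stand beside a result where it changed a call.

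Alternatives set before the data were examined were median-of-ratios and upper-quartile factors, 2 other filters on low counts, each library left out in turn, the replicate block, DESeq2 1.42.0, limma-voom, stricter thresholds, and fits without receptor segments or without genes within 10 Mb of Chd4 and Cd79a. The fit without receptor segments also left out other short features of the heavy-chain locus. List tests were not run with the GC and length corrections. Corrections for GC content and gene length (loess, span 0.4) and a block for Y-linked reads were added after the data were seen. GC content came from the longest GENCODE M21 transcript of each ID and was known for 96.1% of tested genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.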

Results

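The data describe pro-B cells, the B-cell precursors in which the immunoglobulin heavy-chain locus is rearranged. They were sorted from bone marrow as CD19- and c-Kit-positive cells without lineage markers, surface IgM, IgD or CD25. In the cKO group the floxed Chd4 gene was deleted by a Cre recombinase of Cd79a, a gene expressed from the pro-B stage, and WT littermates served as controls. Each group had 3 libraries, called biological replicates in the labels and independent RNA samples in the series text. The WT libraries held 27922612, 30863754 and 22626801 counts and the cKO libraries 29180316, 23474654 and 27635800, in the order of their replicate numbers. The 10 most abundant genes took between 3.27% and 3.52% of the counts of any library.

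The first question was whether the targeted gene followed the labels. Chd4, which encodes a chromatin-remodelling ATPase of the NuRD complex, fell to 0.50 of its WT level (log2 fold change -1.0, SE 0.11, edgeR adjusted p = 0.000129). It lies on chromosome 6 at 125045999 to 125080609 (mm9, Ensembl gene ENSMUSG00000063870). Its level was 1268, 1416 and 1272 CPM in the WT libraries and 587, 609 and 781 CPM in the cKO libraries, so that the groups did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows). The count sums reads over all exons, and the labels do not say which exons were deleted, so reads of a recombined transcript would still be counted. Cd79a, the signalling chain of the pre-B receptor and the gene that drives the Cre, fell from 799 ± 75 to 348 ± 18.6 CPM (SD, n = 3, fold 0.436, edgeR adjusted p = 8.28e-06). The Cre is inserted at Cd79a, so an effect of the insertion on this gene cannot be told apart from an effect of Chd4 loss. An effect of the Cre, or of the lower Cd79a level, on other genes was not tested.

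Genes that mark the pro-B stage stayed abundant in both groups. Whether the gate held the same mix of earlier and later cells in both groups was not tested. Il7r, the receptor chain for interleukin 7, rose 2.08-fold, from 299 ± 19.2 to 621 ± 89.5 CPM (SD, n = 3, edgeR adjusted p = 6.37e-05). Kit, which was part of the sorting gate, rose 1.69-fold, and the surrogate light-chain genes Igll1 and Vpreb1 fell to 0.785 and 0.808 of WT (edgeR adjusted p = 0.000604, 0.00552 and 0.0124). Cd19, also part of the gate, was at 1040 ± 59.4 CPM in WT and 1012 ± 52 CPM in cKO (SD, n = 3) and did not pass the test (edgeR adjusted p = 0.717). The recombinase gene Rag1 rose 1.41-fold (edgeR adjusted p = 0.0175), while Rag2 had a log2 fold change of -0.14 (SE 0.13, edgeR adjusted p = 0.409). Pax5, which holds B-cell identity, rose 1.16-fold (edgeR adjusted p = 0.0430). The B-lineage factor Ebf1 (log2 fold change 0.23, SE 0.09) and the terminal transferase gene Dntt (-0.20, SE 0.09) missed the threshold at edgeR adjusted p of 0.0746 and 0.116. With the replicate block both passed, at edgeR adjusted p of 0.0349 and 0.0294, within ranges of 0.0112 to 0.254 and 0.0294 to 0.388 over the alternatives. Ebf1 also passed with DESeq2 (adjusted p = 0.0340), with the GC correction (0.0289) and with a filter of 5 CPM in 3 libraries (0.0462).

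Several calls near the threshold were lost with fewer libraries, while the folds kept their direction. With single libraries left out the log2 fold change of Pax5 was 0.17 to 0.26 (0.21 with all), that of Rag1 0.39 to 0.66 (0.50 with all) and that of Vpreb1 -0.37 to -0.26 (-0.31 with all). Among genes not called with all libraries, that of Ebf1 was 0.14 to 0.28 and that of Rag2 -0.27 to -0.015. The Pax5 call was lost without WT replicate 2 or 3 or cKO replicate 2 or 3 (edgeR adjusted p = 0.137, 0.131, 0.150 and 0.119, range over all alternatives 0.0205 to 0.150). It was also lost with no filter on low counts (0.0835), with upper-quartile factors (0.0666), without receptor segments (0.0507) and with the block for Y-linked reads (0.0505). The Rag1 call was lost without WT replicate 2 or 3 or cKO replicate 1 or 2 (0.0705, 0.0588, 0.0648 and 0.0534, range 0.000146 to 0.0705), and that of Vpreb1 without WT replicate 2 (0.0572, range 0.000857 to 0.0572). Dntt passed without cKO replicate 1 (0.0488).

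**Figure D1:**
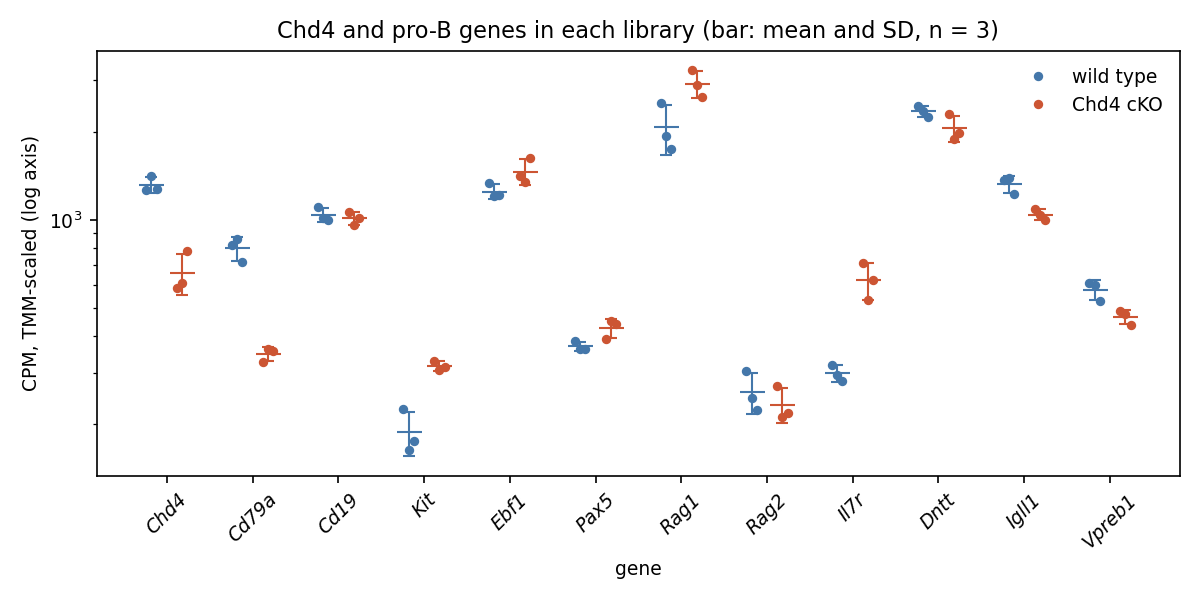
TMM-scaled CPM (log axis) of Chd4 and 11 pro-B genes in each of the 3 WT libraries (blue) and 3 cKO libraries (red), with the mean and SD as bars. The Chd4 points lie at 1268 to 1416 CPM in WT and 587 to 781 CPM in cKO, and those of Cd19 overlap between the groups.

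The main comparison asked which genes differ between cKO and WT pro-B cells. The largest rises among genes with a mean of at least 5 CPM and a symbol not of the Gm or Rik kind were found at genes that were nearly silent in WT cells. Lama5, a laminin chain of basement membranes, rose 252-fold, from 0.187 ± 0.089 to 50.5 ± 2.52 CPM (SD, n = 3, log2 fold change 7.98, SE 0.18, edgeR adjusted p = 3.27e-08). The epithelial membrane gene Emp2 rose 136-fold, the monocarboxylate transporter-family gene Slc16a11 122-fold, and Chga, a protein of neuroendocrine secretory granules, 113-fold. The imprinted noncoding RNA Meg3 had 2 counts over the WT libraries and 2492 over the cKO libraries, a ratio of 1272 (95% counting interval 352 to 10508). Iglon5, a neural adhesion gene, had 1 and 1239 counts, a ratio of 1265 (227 to 49995), and its log2 fold change of 9.85 was 11.67 without WT replicate 2, which held the 1 count.

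Among genes with a mean of at least 5 CPM and a symbol other than of the Gm or Rik kind, the largest fall was that of the collagen gene Col5a3. It fell from 21.4 ± 4.20 to 0.180 ± 0.066 CPM (SD, n = 3, 119-fold, log2 fold change -6.89, SE 0.26, edgeR adjusted p = 2.20e-07). The calcium-channel subunit Cacna2d1 fell 78.5-fold, the sarcomere gene Myom2 22.2-fold and the sodium-channel subunit Scn4b 20.6-fold, the last from 354 ± 57.9 to 17.1 ± 1.26 CPM (SD, n = 3). Without cKO replicate 1 the log2 fold change of Cacna2d1 was -7.51 against -6.29, so that its rank below Col5a3 (-7.20 to -6.73 with single libraries left out) is not settled. Enpep, an aminopeptidase used as a marker of B-cell precursors, fell 16.3-fold, and Tnfrsf8 (CD30) fell 11.1-fold. Below that level the potassium-channel gene Kcna5, which lies within 10 Mb of Chd4, had 608 counts over the WT libraries and 0 over the cKO libraries, at least 199-fold lower.

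Of the 14063 genes tested, 6119 (43.5%) changed, 3303 higher and 2816 lower in cKO (edgeR, adjusted over all genes tested). More rises than falls were large. Called rises beyond 2-fold numbered 1468 against 698 falls, and those beyond 8-fold 371 against 51. At 7567 genes (53.8%) the cKO and WT libraries did not overlap, where chance gives 10%. The first principal component held 80.6% of the variance and separated the groups. A test against a log2 fold change of 1 called 1276 genes, 961 higher and 315 lower.

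The title of the series names transcriptional repression, and the direction of change was therefore compared between genes of low and high level. In the lowest of the 4 expression bins, with levels up to 3.48 CPM, 922 of 1345 called genes (68.6%, Wilson 95% interval 66.0 to 71.0) were higher in cKO. In the other bins the share higher was 49.8% (47.4 to 52.2) of 1727 genes, 48.5% (46.0 to 50.9) of 1624 and 51.6% (49.0 to 54.2) of 1423. Genes of a bin are not independent of each other, so the intervals cover counting error only.

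**Figure D2:**
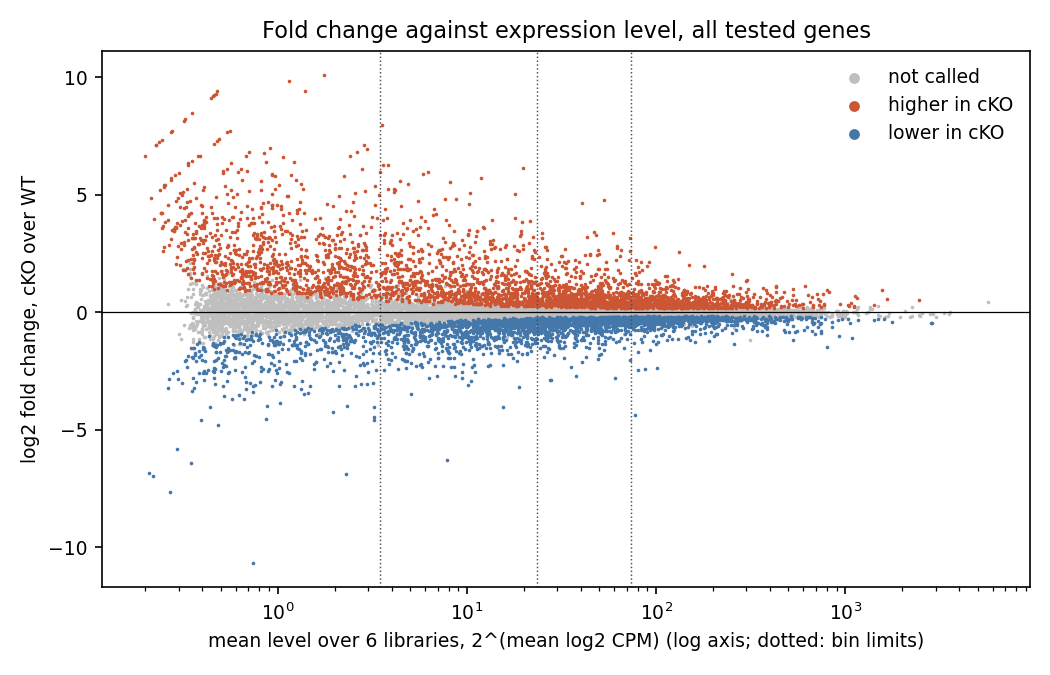
Log2 fold change of cKO over WT against the mean level over the 6 libraries (2 to the mean log2 CPM, log axis) for the 14063 tested genes, with rises in red, falls in blue and genes not called in grey. Dotted lines bound the 4 bins, and the lowest bin holds 922 called rises and 423 called falls.

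Members of chromatin complexes went both ways, and camera called none of the 3 lists (adjusted p = 0.573 for NuRD, 0.609 for polycomb and 0.787 for other remodellers). Among 15 NuRD subunits 6 rose and 4 fell, with Chd4, the targeted gene, among the falls. The paralogue Chd3 rose 1.99-fold, from 376 ± 21.0 to 748 ± 32.9 CPM (SD, n = 3, edgeR adjusted p = 8.26e-06), Chd5, a paralogue known from neurons and testis, rose from 0.168 ± 0.032 to 5.41 ± 1.63 CPM (30.8-fold), and Gatad2a rose 1.77-fold. Of 18 polycomb genes 4 rose and 5 fell. The accessory subunit gene Phf19 rose 2.46-fold and Phc2 1.69-fold, while Ezh2, the methyltransferase of the second polycomb complex, fell to 0.563 of WT, from 637 ± 2.73 to 359 ± 36.2 CPM (SD, n = 3). Among 19 other remodellers 5 rose and 3 fell, with Smarca1 37.2-fold higher from a low level, Chd7 2.56-fold and Smarcd1 1.44-fold higher. Adjusted over the list alone, these counts were the same.

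More B-lineage transcription factors rose than fell, and camera did not call the list (adjusted p = 0.325). Of 22 factors 12 rose and 2 fell, and adjusted over the list alone 13 rose and 5 fell. Irf4, which acts at the pre-B and plasma-cell stages, rose 1.80-fold, from 322 ± 2.70 to 578 ± 17.9 CPM (SD, n = 3), and Foxo1, an activator of the Rag genes, rose 1.69-fold. Tcf3, which encodes the E2A proteins, fell to 0.642 of WT, from 1059 ± 19 to 680 ± 22.8 CPM (SD, n = 3). Among 19 genes of the pro-B and pre-B receptor 4 rose and 11 fell, with Cd79a, the site of the Cre, among the falls. Vpreb2 fell 3.81-fold and Fcrla 2.76-fold, while Cd38 rose 3.14-fold. Of 16 V(D)J recombination genes 3 rose and 3 fell, among them the end-joining ligase Lig4, which fell 2.47-fold from 120 ± 6.63 to 48.6 ± 6.85 CPM (SD, n = 3), its partner Xrcc4 (1.37-fold lower) and Nhej1 (1.65-fold higher). Adjusted over the list alone, the counts of the receptor and recombination lists were the same.

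Genes of later B-cell stages went both ways. Of 18 members 6 rose and 6 fell, with the costimulatory ligand Cd86 up 9.67-fold and the chemokine receptor Ccr7 up 3.57-fold, and with the tetraspanin Cd37 at 0.618 of WT. In the interleukin-7 receptor and STAT5 pathway 5 of 19 members rose and 5 fell (5 and 7 adjusted over the list alone). Stat5a fell to 0.350 of WT, from 84.7 ± 3.23 to 29.6 ± 1.23 CPM, and the kinase gene Jak3 to 0.309, while the feedback inhibitor gene Socs2 rose 3.30-fold (SD, n = 3, edgeR adjusted p = 4.97e-07, 4.79e-05 and 3.79e-06). Of 32 cytokine and receptor genes 5 rose and 8 fell, among them Crlf2, a chain of the thymic stromal lymphopoietin receptor (2.26-fold lower), and Il27ra (2.14-fold lower). Il2ra, which encodes the CD25 that the sort selected against, fell from 9.37 ± 1.16 to 0.567 ± 0.371 CPM (SD, n = 3), at a log2 fold change of -4.00 that was -4.72 without cKO replicate 1. The later-stage and cytokine counts were the same adjusted over the list alone.

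Most genes of the cell cycle and of ribosome production were not called, and the called changes were small. Camera called none of the 3 lists (adjusted p = 0.326 for G2/M, 0.325 for S phase and 0.25 for ribosome biogenesis). None of 20 G2/M genes rose and 5 fell (0 and 4 adjusted over the list alone). Cyclin A2 (Ccna2) fell to 0.742 of WT, from 473 ± 51.2 to 351 ± 15.4 CPM (SD, n = 3). Cenpe and Kif11 were at 0.805 and 0.820 of WT. Of 20 S-phase genes 1 rose and 4 fell, with Uhrf1 at 0.734, Rrm2 at 0.777 and Pcna at 0.818 of WT. Of 20 ribosome biogenesis genes 1 rose and 6 fell, among them Nop2 (0.619 of WT), Gnl3 (0.701) and Nop58 (0.788). Nop2 starts at 125081901 on chromosome 6, beside Chd4 (125045999 to 125080609) and on the same strand. An effect of the targeted allele on Nop2 was not tested. The S-phase and ribosome counts were the same adjusted over the list alone. The calls of Cenpe, Kif11, Pcna and Nop58 were lost without WT replicate 2 (edgeR adjusted p = 0.0514, 0.0927, 0.0667 and 0.0550). Their log2 fold changes in that fit were -0.33, -0.27, -0.22 and -0.29, against -0.31, -0.29, -0.29 and -0.34 with all libraries. Those of Cenpe and Kif11 were also lost without WT replicate 3 or cKO replicate 1 or 2, and that of Pcna without cKO replicate 2. The GC correction ended the calls of Cenpe (0.0502), Kif11 (0.0643) and Nop58 (0.0538), at log2 fold changes of -0.26, -0.23 and -0.28 against -0.31, -0.29 and -0.34. Over all alternatives these p ranged from 0.000973 to 0.0743, 0.00323 to 0.102, 0.00257 to 0.0667 and 0.000588 to 0.0550.

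More p53 targets and BCL2-family genes rose than fell, and camera called neither list (adjusted p = 0.325 and 0.326). Of all 14063 tested genes 3303 rose and 2816 fell. Of 19 tested p53 targets 9 rose and 3 fell, with the stress-response gene Sesn2 up 2.14-fold, Phlda3 2.39-fold and the apoptosis effector Bax 1.43-fold, from 41.4 ± 2.39 to 59.2 ± 1.84 CPM (SD, n = 3). Of 14 genes of the BCL2 family 7 rose and 3 fell, including the pro-apoptotic Bcl2l11 (1.81-fold higher), Bid (1.5-fold higher, within 10 Mb of Chd4) and Bok (1.66-fold lower). The BCL2 list was fixed with anti-apoptotic members such as Bcl2 and Mcl1 as well, and it shares 5 members with other lists. Of 24 interferon-stimulated genes 10 rose and none fell, among them Ifih1 (2.04-fold), Oas1a (1.78-fold) and Stat2 (1.5-fold). Of 25 adhesion and migration genes 12 rose and 4 fell. F11r, a junctional adhesion molecule, rose from 6.04 ± 0.670 to 41.6 ± 3.34 CPM (SD, n = 3, 6.87-fold, edgeR adjusted p = 3.22e-07), and the chemokine Ccl4 rose 5.84-fold. Adjusted over the list alone, the counts of these lists were the same.

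Some genes typical of nerve and muscle rose, and most members of those lists were below the filter. Of 23 neuronal genes 8 passed the filter, and of these 5 rose and 2 fell. The neurofilament gene Nefh rose 6.72-fold, from 5.36 ± 0.501 to 36.1 ± 4.41 CPM, and the synaptic scaffold gene Dlg4 3.86-fold, while Nrxn1 fell 11.9-fold (SD, n = 3). Of 25 sarcomere genes 10 passed, and 5 rose and none fell (6 and 0 adjusted over the list alone), with Tnni1 at 0.071 and 2.55 CPM, Tnnt3 3.15-fold higher and Acta2 2.91-fold higher. The sarcomere gene Myom2, which is not in the list, fell 22.2-fold. Camera called neither list (adjusted p = 0.104 for neuronal and 0.325 for sarcomere genes). The counts of neuronal genes were the same adjusted over the list alone.

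Markers of other blood lineages did not move as 1 block. Of 14 tested T-cell genes 6 rose and 2 fell, with Notch3 up 7.72-fold and the adaptor gene Lat 2.49-fold, and Cd27 down 4.55-fold. Cd27 lies at 125182640 to 125187028 on chromosome 6, near the end of Chd4 at 125080609. An effect of the targeted allele on Cd27 was not tested. Of 12 dendritic-cell genes 7 rose and 2 fell, among them Cox6a2 (38.3-fold higher), Zbtb46 (6.29-fold higher) and Ly6d (2.69-fold lower), the last also a marker of early B-cell commitment. Of 12 plasma-cell genes 6 rose and 1 fell. Prdm1, the plasma-cell repressor Blimp-1, rose from 2.35 ± 0.336 to 14.1 ± 2.47 CPM (SD, n = 3, 5.99-fold, edgeR adjusted p = 7.04e-06), Eaf2 rose 4.35-fold and Xbp1 2.15-fold. Of 13 stem and progenitor genes 2 rose and 5 fell. Ly6a (Sca-1) rose 14.6-fold, from 5.64 ± 0.183 to 82.3 ± 9.67 CPM (SD, n = 3), and Satb1 1.72-fold, while Hoxa7 fell 3.86-fold. Of 10 natural killer and innate lymphoid genes 2 rose and 3 fell, with Prf1 5.53-fold and Klrb1c 2.78-fold lower (the latter within 10 Mb of Chd4) and Nkg7 2.22-fold higher. Adjusted over the list alone, these counts were the same.

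Transcripts typical of other bone-marrow cells were counted in every library, from a source that was not tested. The neutrophil gene S100a9 was measured at 445, 408 and 279 CPM in WT and 517, 259 and 241 CPM in cKO. Of 22 neutrophil and monocyte genes 3 rose and none fell, namely the integrin gene Itgam (2.08-fold), Cd68 (1.56-fold) and Cebpb (1.78-fold). Of 15 erythroid genes 1 rose (Car2, 1.76-fold), of 8 megakaryocyte and mast-cell genes 1 rose (Gp5, 2.22-fold), and of 11 stromal and endothelial genes Kdr rose 6.43-fold and Emcn fell 2.32-fold. Of 16 handling-stress genes 4 rose and 1 fell. Atf3 was 16.5-fold higher on average, at 3.92, 21.0 and 67.5 CPM in the cKO libraries, with a log2 fold change of 4.04 that was 2.72 without cKO replicate 3, and its call was lost with limma-voom (adjusted p = 0.118, range over the alternatives 4.60e-05 to 0.118). Ier3 rose 3.14-fold and Ier2 1.29-fold. Neither tested sex-linked gene was called, with log2 fold changes of -0.21 for Xist and -0.42 for Tsix (SE 1.85 and 0.87). Replicate 3 of both groups carried Y-linked reads and almost no Xist, so that sex was balanced between the groups. Adjusted over the list alone, the counts of these lists were the same.

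**Figure D3:**
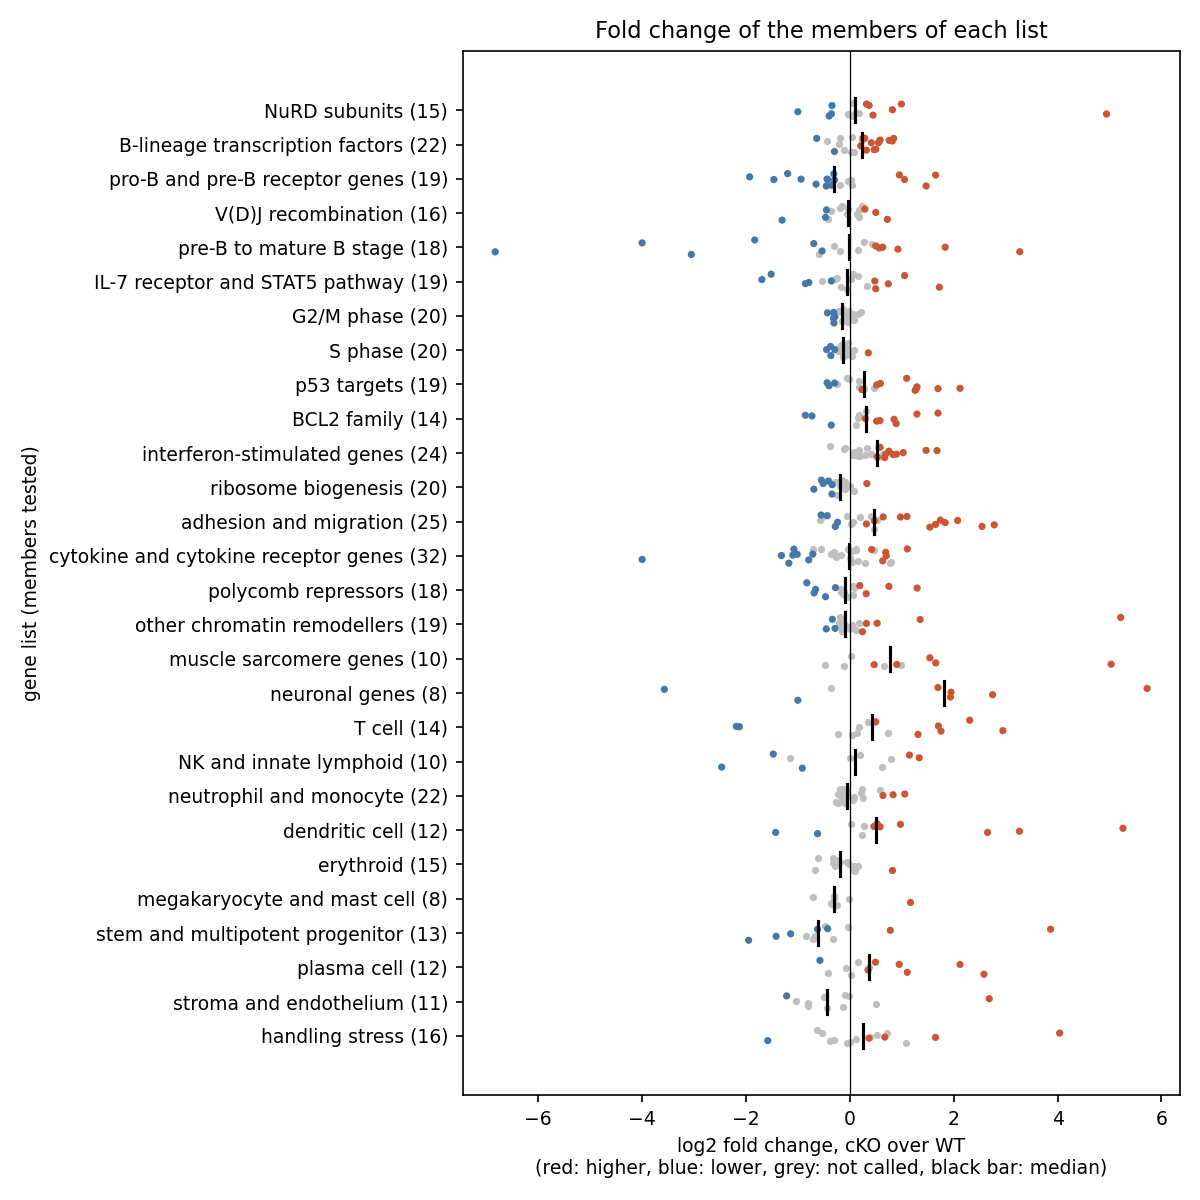
Log2 fold change of cKO over WT for the tested members of the 28 lists with at least 5 tested members, one point per gene, with rises in red, falls in blue, genes not called in grey and the median of each list as a black bar. Most lists hold points on both sides of 0, and the interferon-stimulated list holds 10 rises and no fall.

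As sets, no list was called against the other tested genes at the main setting. Camera called 0 of 28 lists (lowest adjusted p = 0.0922, 5 lists at an unadjusted p under 0.05), and with an estimated correlation it called 0 as well (lowest adjusted p = 0.790, 0 lists at an unadjusted p under 0.05). The adhesion and neuronal lists were nearest to the threshold, both upward, at adjusted p of 0.0922 and 0.104 (0.891 and 0.790 with an estimated correlation). With the replicate block, camera called 3 lists, all upward: interferon-stimulated, adhesion and neuronal genes, each at an adjusted p of 0.0339. These calls used the preset correlation of 0.01. At the main setting the correlation estimated for these 3 lists was 0.919, 0.315 and 0.081, in that order. Over the alternatives run for lists, fry and the estimated correlation included and the GC and length corrections not, their adjusted p ranged from 0.0339 to 0.988, from 0.0043 to 0.891 and from 0.00102 to 0.790. Without a filter on low counts camera called 5 lists. With single libraries left out adhesion passed without WT replicate 1 (0.0361), cKO replicate 2 (0.0400) or cKO replicate 3 (0.0297), and the neuronal list without cKO replicate 3 (0.0382).

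Fry, which asks whether a list's own genes move and makes no comparison with other genes, called 10 lists in 1 direction. The lists that moved upward were B-lineage factors, p53 targets, the BCL2 family, adhesion, sarcomere, neuronal, T-cell, dendritic-cell and plasma-cell genes, and the pro-B and pre-B receptor list moved downward. Its test for change in either direction called 24 lists. Median, mean and camera direction differed in sign for other remodellers (median -0.09, mean 0.31, upward), natural killer genes (median 0.10, mean -0.19, downward) and neutrophil genes (median -0.06, mean 0.10, downward).

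The last comparison set variable segments far from the heavy-chain constant genes against those near them, since distal and proximal segments differ in how they reach recombination. Gene-level counts do not tell transcripts of rearranged segments from those of unrearranged ones, so segment usage was not measured. Only 4 distal (Ighv1) and 4 proximal (Ighv5 and Ighv2) IDs carried a symbol, so the sums cover a small part of each family. They do not stand for the whole locus, where the sum over all segments was 0.617 and 0.246 of WT in the 2 windows of 500 kb nearest the constant genes and 3.02 and 3.22 times WT in the 2 farthest, in windows chosen after the data were seen. A few segments carried the farthest sum, since 6 of 16 tested segments were called there and the median log2 fold change was 0.17. The distal sum was 5.07 ± 0.089 CPM in WT and 7.26 ± 0.132 CPM in cKO, or 1.43 times as high (SD, n = 3, exact permutation p = 0.1, the smallest possible). The proximal sum was 8.61 ± 1.09 and 8.80 ± 1.17 CPM (SD, n = 3, exact permutation p = 1), of which Ighv5-2 alone made up 7.64 and 8.30 CPM, and the ratio of distal to proximal was 1.41 times as high in cKO (exact permutation p = 0.1). Of the 3 distal segments tested 1 rose, Ighv1-47 (from 1.44 to 3.42 CPM, which is most of the rise of the distal sum, 2.36-fold, edgeR adjusted p = 0.00104). Neither of the 2 proximal segments tested passed, with log2 fold changes of 0.11 for Ighv5-2 and -0.91 for Ighv2-6-8. With single libraries left out these ranged from 0.011 to 0.22 and from -1.24 to -0.72. Ighv2-6-8 passed with the replicate block (edgeR adjusted p = 0.0469) and without WT replicate 2 (0.0285), within a range of 0.0285 to 0.279. The counts for both lists were the same adjusted over the list alone.

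**Figure D4:**
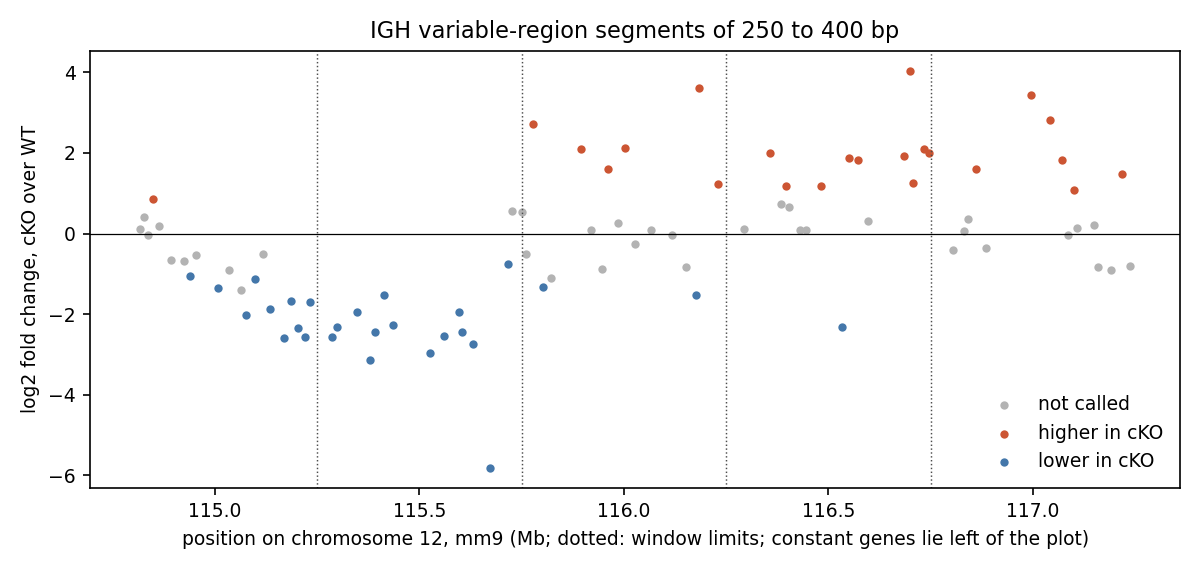
Log2 fold change of cKO over WT for the 87 tested features of 250 to 400 bp in the variable region of the heavy-chain locus, by position on chromosome 12 (mm9), with rises in red, falls in blue and features not called in grey. Dotted lines bound 5 windows chosen after the data were seen, and the constant genes lie to the left, where 10 and 14 features of the first 2 windows fell.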

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

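The corrections for GC content and gene length and the block for Y-linked reads were chosen after the data were seen, and the other alternatives before. The number of changed genes was 6119 and lay between 4833 and 7116 under the other normalizations, filters, tools, corrections and left-out libraries. In none of them was a gene called in both fits with opposite signs. The test against a log2 fold change of 1 called 1276 genes (961 higher, 315 lower), fewer by construction, and at an adjusted p under 0.01 the genes lower in cKO numbered 1843. Chd4 stayed called, with log2 fold changes between -1.14 and -0.94. The replicate block gave 7116 changed genes and called 3 lists against 0 without it. Among named genes it added Ebf1, Dntt and Ighv2-6-8 and changed no other call. The number of lists called was 5 with no filter on low counts, 10 by fry, and between 0 and 2 with single libraries left out. The cause of these differences was not tested.

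In the lowest expression bin the share of called genes higher in cKO was between 68.6% and 72.5% with single libraries left out and 71.5% with DESeq2. In the third bin it was 51.7% after the GC correction and 51.7% after the length correction, against 48.5%. In the highest bin it was between 46.0% and 54.6% with single libraries left out (the lowest without WT replicate 1) and 56.2% after the GC correction, so no direction was read from it. The distal segment sum was 1.48 times as high in cKO as a share of all counts in the heavy-chain locus, against 1.43 in CPM. As the mean of within-number ratios, under the pairing by replicate number, it was 1.43.

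Signs that turned belonged to values that were not called. Cd19 ranged from -0.087 to 0.0015 with libraries left out and was 0.0031 after the length correction, Xist ranged from -0.79 to 0.43 and Tsix from -0.95 to 0.22. For lists, camera's direction turned as follows, with its adjusted p. With some of the 6 libraries left out it turned, with the range over all 6, for later B-cell stages (0.666 to 0.952), neutrophil (0.333 to 0.962), erythroid (0.336 to 0.962), stromal (0.488 to 0.989) and handling genes (0.296 to 0.962). With a CPM of at least 5 in at least 3 libraries it was 0.517 for later B-cell stages and 0.990 for neutrophil, erythroid, stem-cell and stromal genes. With the replicate block it was 0.853 for later B-cell stages and 0.926 for neutrophil genes, and with the block for Y-linked reads 0.898 and 0.990. By fry it was 0.416 for later stages, 0.795 for neutrophil and 0.919 for erythroid genes. For neutrophil genes it was also 0.906 with no filter, 0.971 with upper-quartile factors and 0.998 without receptor segments. Depth limits the genes nearly silent in 1 group, whose fold rests on a few counts.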

Other observations

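The imprinted list, the gene families grouped by symbol root and the windows of the heavy-chain locus were chosen after the data were seen, as were the tests on marker lists of other cell types and on the heavy-chain locus. Several imprinted genes, normally transcribed from 1 parental copy, were higher in cKO. Of 30 such genes 15 were tested, 10 rose and 2 fell. The list was prompted by Meg3 and H19, so its count is not independent evidence of a direction. H19 rose from 0.351 ± 0.078 to 10.7 ± 3.14 CPM, Peg10 from 3.15 ± 0.852 to 20.8 ± 0.473 CPM and the cell-cycle inhibitor gene Cdkn1c from 3.32 ± 0.335 to 8.32 ± 0.886 CPM (SD, n = 3). Dlk1, which lies beside Meg3, had 3 counts over the WT libraries and 218 over the cKO libraries, a ratio of 74.2 (95% counting interval 25 to 362). Grb10 fell from 8.37 ± 0.707 to 4.96 ± 1.5 CPM (SD, n = 3, edgeR adjusted p = 0.0155) and Airn from 1.60 ± 0.097 to 0.848 ± 0.149 CPM.

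Families named by a shared symbol root went both ways, with camera's direction upward for 58 and downward for 93 of 151. Among 20 Arhgef genes, which encode activators of Rho GTPases, 12 rose and 3 fell, and camera called this family alone (adjusted p = 0.00413, adjusted p = 0.988 with an estimated correlation). Arhgef40 rose from 4.43 to 72.1 CPM and Arhgef17 from 10.6 to 66.9 CPM, while Arhgef5 fell from 41.3 to 14.3 CPM. Of 12 semaphorin genes 9 rose and 1 fell (camera adjusted p = 0.0855), with Sema4a at 13.9 and 73.0 CPM and Sema4b, the gene that fell, at 82.3 and 32.7 CPM. Of 14 Klf transcription factor genes 10 rose and none fell (camera adjusted p = 0.353), among them Klf4, at 22.3 and 42.9 CPM, and Klf13, at 176 and 257 CPM. Families with more falls were the variable segments with a symbol root of Ighv (1 rise and 11 falls among 17, camera adjusted p = 0.0855), Rad (1 and 9 of 18), Trappc (1 and 8 of 14), Nup (0 and 7 of 19) and Nudt (0 and 7 of 19). All of these were picked from the tables by their small p or 1-sided counts.

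Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many genes as the real one, which was the real one itself with 6119, and the highest of the others called 1. With 10 splits no share under 0.05 can be reached. The other 3 splits that part all 3 numbered pairs called 0 genes. Genes within 10 Mb of Chd4 or Cd79a made up 3.35% of the called genes, and 47.7% of them were called against 43.4% elsewhere.

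Among called genes of the lowest expression bin 68.6% were higher in cKO. After each library's trend on GC content or on gene length was removed the share was 69.6% (67 to 72.1) and 69.0% (66.4 to 71.4). This argues against trends shared with better expressed genes as the whole of the pattern. The trends were fitted without the least expressed genes, so a trend confined to those would not be removed. Of all tested genes of the bin, called or not, 58.8% (57.2 to 60.4) had a positive fold change, which argues against unequal power of the test for rises and falls. Against the median of 2.10 of the bin's called rises, the marker lists of neutrophils, red-cell precursors and stromal cells had medians of at most -0.061, and the summed CPM of transcripts abundant in T cells (Cd3 chains and receptor constant genes) and plasma cells (Igkc and Jchain) had log2 ratios of -0.060 and 0.142 with overlapping groups, which argues against these cells. Dendritic cells stay open, although the sorting gate selects against them. The sum of transcripts abundant in them (Cd74, Cst3, H2-Aa, H2-Ab1, H2-Eb1 and Siglech) was higher in every cKO than in every WT library, at a log2 ratio of 0.345. Cd74 and the H2 genes are also in the list of later B-cell stages, so this sum cannot tell dendritic cells from B-lineage cells. A release of silent genes from repression stays open too.

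Neighbouring genes tended to change in the same direction. Of 2259 pairs of adjacent called genes within 100 kb, 60.8% shared direction, against a mean of 50.3% and a maximum of 53.4% in 1000 shuffles of the directions. Pairs on opposite strands, which stranded counting keeps apart, shared direction at 60.1% (shuffle maximum 55.4%), which argues against reads running on into the next gene as the whole cause, and after the GC correction the share over all pairs was 59.8% (shuffle maximum 53.8%). Without receptor segments it was 60.3%. What links the direction of neighbours was not tested.

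Segments of the variable region of the heavy-chain locus split by position. In 5 windows of 500 kb on chromosome 12 (114750001 to 117250000, mm9), counted from the side of the constant gene Ighm, 21, 15, 18, 17 and 16 segments were tested, with 1 rise and 10 falls, 0 and 14, 6 and 2, 10 and 1, and 6 and 0, and with median log2 fold changes of -1.05, -2.43, 0.09, 1.18 and 0.17. The summed CPM in cKO was 0.617, 0.246, 1.85, 3.02 and 3.22 times that in WT, and in the farthest window a few segments carried the sum, among them ENSMUSG00000076732 with 66, 74 and 67 counts in WT and 803, 681 and 729 in cKO. Reads shared by near-identical segments stay open, since such reads were not counted and the total over all 111 segments, 1.53 times as high in cKO, can move for that reason too. Counts too few to give a direction were argued against for the window sums only, in windows chosen after the data were seen. The sums over all segments, called or not, lay at 21.9 to 23.3 CPM in WT and 5.22 to 5.80 CPM in cKO in the second window, and at 21.2 to 23.7 and 68.2 to 76.2 CPM in the farthest (3.22 times as high). The farthest sum gives no direction for the segments there as a set, whose median log2 fold change was 0.17. A few expanded clones were not tested, and transcripts of rearranged and unrearranged segments were not told apart.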
